A study of Homo sapiens with 35 samples.

How the data were processed

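Contacts of chromatin with the nuclear lamina were measured by DamID in single cells of clone 5-5 of KBM7, a human leukaemia cell line, which the labels give as diploid (2N). In DamID, the Dam adenine methylase of bacteria is fused to a protein of interest, here lamin B1, a filament protein of the lamina at the inner side of the nuclear envelope, and DNA near the fusion protein gains methyl groups at GATC sites. Per the labels' protocols, methylation was induced with 0.5 nM Shield1 for 15 h, and the 2% smallest cells positive for both Fucci cell-cycle markers were sorted singly. Per the same protocols, DNA was digested with DpnI, which cuts methylated GATC sites, ligated to adaptors and amplified with 21 extension steps.

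The deposited table holds ratios, and per the file headers each value is the ratio of observed to expected reads (OE) in a 100-kb bin of 1 cell. The submitters' processing notes name cutadapt, Bowtie2 2.1.0 and the genome build hg19, and all positions below are hg19, counted from 1. How the expectation was made, how reads were filtered and whether duplicates were removed are not given in the sources used here. No cells with unfused Dam were used here, so local chromatin accessibility and mappability enter the values as far as that expectation leaves them in.

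The labels list 35 samples of 1 kind, and 32 of them matched a column by the sample number in the title. The other 3 (samples 12, 14 and 16) were not analysed here. The table covers 30376 bins, of which 26584 had a value in every cell and were used. The other 3792 bins (12.5%) had no value in any cell and included all 1464 bins of chromosome 8 and 289 bins of chromosome 15 (61000001 to 89900000). Chromosomes 9 and 22 are given in the table as 9:22 and 22:9, with last positions of 161500000 and 31200000. KBM7 carries the Philadelphia translocation between these chromosomes, and the table's names were kept because no hg19 annotation was used here to place the junction.

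Within a bin, the values of a cell were whole multiples of the value of 1 read. Whole reads were recovered from these steps, and 100% of the values came out whole within a tolerance of 0.01 reads. The step of a bin was the largest that divides all of its values, so this follows from the method and does not check it. A bin whose reads all share a factor comes out with too few reads and too few expected reads. Recovered reads per cell were used for depth, for thinning and for the expected reads per bin. Reads after PCR are not independent molecules, so read numbers describe sequencing depth and not the number of methylated fragments.

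A bin was called in contact with the lamina in a cell where its OE was 1 or more. The cells are diploid and methylation was induced over 15 h. A call can therefore come from either copy of a chromosome and from any time in those 15 h. The contact share of a cell was the percentage of used bins in contact, and the contact frequency of a bin was the percentage of cells in which it was in contact. The number of cells in contact was tested per bin with an exact two-sided Poisson-binomial test against the contact shares of the cells, with Benjamini-Hochberg adjustment over 26584 bins and a threshold of 0.05. Chromosomes were compared with all other used bins of the same cell, and regions near the centromere or a chromosome end with the rest of the bins, by two-sided sign-flip permutation tests over cells with 100000 resamples. Adjustment by Benjamini-Hochberg was made over 22 chromosomes and over the 2 kinds of region.

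The centromere was taken as the longest stretch of bins without values on a chromosome. On chromosome 15 that stretch was the long-arm part without values, and the stretch at the start of the chromosome (1 to 20000000) was used in its place. Runs of adjacent contacted bins, correlations of contacts between bins and overlaps between cells were compared with 100 randomised tables. The randomisation swapped contacts between cells so that the contact frequency of each bin and the number of contacts of each cell were kept, for runs also on each chromosome. The planned rotation test of contact frequency against OE is not reported, because rotations leave out that both come from the same values.

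Regions were named by a rule set with the tests and alternatives before the data were examined: the 8 longest stretches of adjacent bins with a contact frequency of at least 80%, and the 8 longest with a frequency of 0%. Chromosomes were named as the 3 highest and 3 lowest in contact share, with 15, 18, 19 and X. Other chromosomes and stretches named in the text were chosen after their values were seen. The planned analyses of gene density, of gene lists, and of chromosome 8 with part of chromosome 15 were not run, the last because those bins hold no values. The gene table at hand is of another genome build than the bins, so no gene is named here.

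Alternatives were OE limits of 0.5, 2 and above 0, autosomes only, leaving out bins at 0 in every cell, leaving out the 8 sparsest cells, distances of 2 and 10 Mb, runs joined across 1 bin, bins of 30 to 70% contact frequency, and Pearson correlation of log2(OE + 0.1). After the data were seen, leaving out 3 cells under 2000 reads, thinning the other 29 cells to 40279 reads each, and leaving out 523 bins with low expected reads were added. Under an alternative, a tested value was compared by its direction and its side of the threshold, a count of bins or chromosomes was taken as unmoved within 1.5 times, and the contact share and the median overlap of cells within 1 SD. The labels name no separate cultures, so all p-values rest on these cells alone and none compares cultures or conditions. Those of sign-flip tests and of correlations with reads measure only the spread between these cells, which may be technical. The p-value of a bin compares its number of contacts with placement by the contact shares of the cells. Those against randomised tables measure only the spread between such tables.

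The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The procedures were tested on simulated data with 26584 bins. Recovered reads equalled the simulated reads for 99.99% of values above 0. The simulated reads were independent draws without PCR copies, so bins whose reads share a factor were not tested. Read numbers of bins with few reads may therefore be too low. The bin test called 96.5% of bins whose odds of contact were raised 8-fold, 16.5% of those raised 3-fold, 18.5% of those lowered 8-fold and 0.0077% of unchanged bins. Few bins were changed in that simulation, so the adjustment set a stricter limit there than in the data, where most bins were called. In the data, the Poisson-binomial test called bins up to an unadjusted p of 0.0318. The simulated rates therefore do not describe the calls in the data, where more unchanged bins would pass. Blocks of 10 bins planted together gave an excess correlation of 0.364 at up to 1 Mb, and independent bins gave 0.000158.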

Results

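Lamina contacts were mapped in 32 single cells of 1 group, diploid KBM7 clone 5-5, at 100-kb resolution. The table held no control cells and no second condition, so the comparisons are between regions of the same cells and between cells. Recovered reads ranged from 985 to 258225 per cell with a median of 120164. In 29 cells, with 40279 to 258225 reads, 1 read gave a median OE of 0.094 to 0.605. Cells 13, 15 and 17 had only 985, 1221 and 1755 reads, 1 read gave a median OE of 13.7 to 24.9, and every bin with a read counted as a contact.

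Bins with an OE of at least 1 made up 22.1 to 36.0% of the used bins in 29 of the 32 cells. The mean OE was near 1 in every cell (0.876 to 1.00). The share therefore depends on how the reads of a cell spread over bins and does not measure its total signal. The contact share was 26.3% ± 8.08 of the bins (SD, n = 32), and 28.6% ± 3.99 (SD, n = 29) without the 3 shallow cells, whose shares were 3.51 to 5.99%. Cells with more reads had larger contact shares. Over the 29 deeper cells, Pearson's r of contact share with log10 reads was 0.855 and Spearman's rho 0.874 (permutation p = 1e-05 for both, the smallest that 100000 resamples can give; 1.33e-05 after adjustment over 4 relations), and r was 0.947 without the 2 cells farthest from the median depth. The share depended on the limit that defines a contact, at 44.6% with any read counted and 17.2% with an OE of at least 2.

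**Figure D1:**
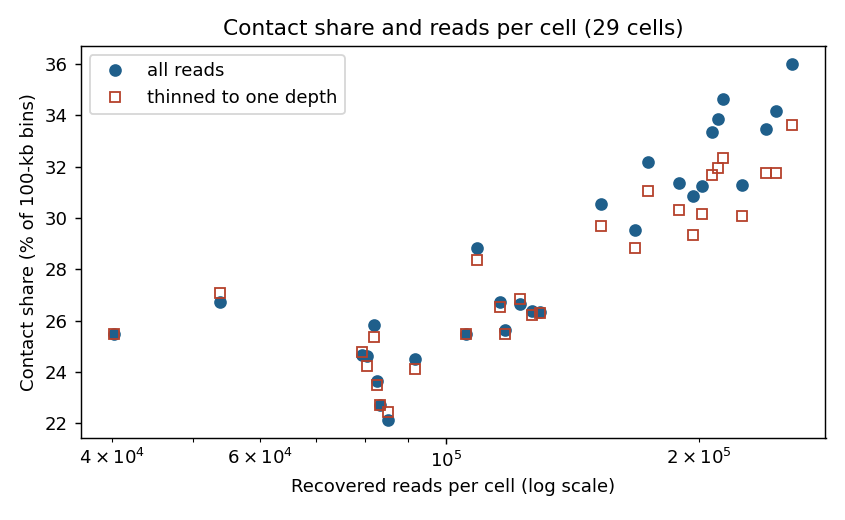
Contact share (% of 100-kb bins, vertical axis) against recovered reads per cell (log scale, horizontal axis) in the 29 cells with at least 40279 reads, from all reads (filled circles) and after thinning every cell to 40279 reads (open squares). The shares lie between 22.1 and 36.0% with all reads and between 22.4 and 33.6% after thinning.

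The series asks how lamina interactions are laid out in individual cells. Most of the genome fell into regions that touched the lamina in no cell or in most cells. Of the 26584 bins, 11165 (42.0%) were in contact in no cell, against 1.35 bins on average (0 to 5) when the contacts of each cell were placed at random. At the other end, 2241 bins (8.43%) were in contact in at least 80% of the cells, against 0 in every random placement, and 3 bins were in contact in all 32 cells. Contact frequencies of 20 to 80% were found in 8468 bins (31.9%), against 20745 at random. From the cells' own contact shares, 8.42 cells in contact were expected per bin. The exact Poisson-binomial test called 8059 bins (30.3%) in contact more often than that, each in at least 15 cells, and 14484 bins (54.5%) less often, each in at most 3 cells. The number of bins at 80% or more was 3774 without the 3 shallow cells, 4018 without the 8 sparsest cells, and 7099, 4758 and 261 with contact limits of any read, 0.5 and 2. With any read counted, 1204 bins were in contact in no cell.

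**Figure D2:**
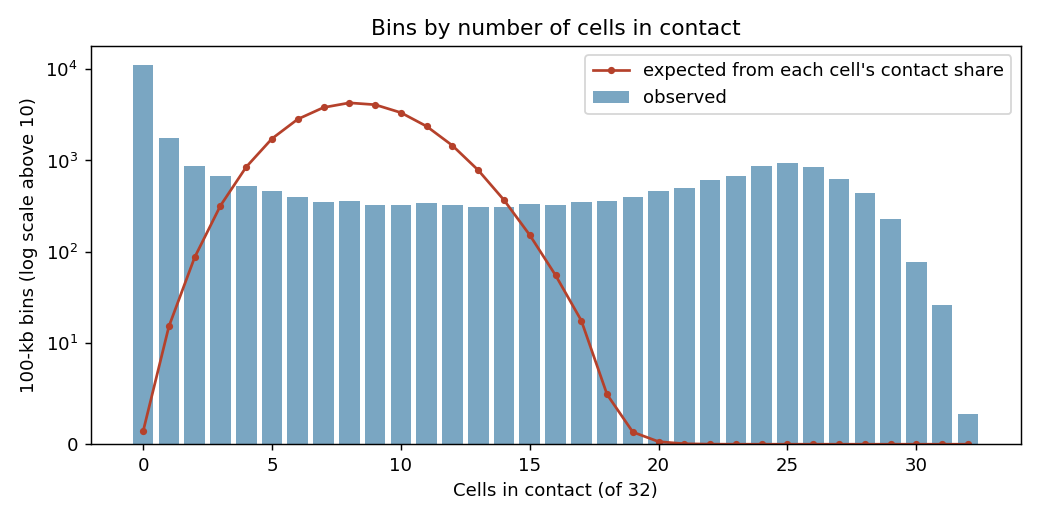
Number of 100-kb bins (vertical axis, log scale above 10) by the number of cells in which they were in contact (horizontal axis, 0 to 32). Bars are the observed bins and the line is the number expected from each cell's contact share, with 11165 bins observed in no cell and an expected mean of 8.42 cells per bin.

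Chromosomes differed widely in how much of their length touched the lamina. Chromosome 4 had the highest share, 41.5% ± 13.0 of its bins (SD, n = 32), followed by X with 37.1% ± 11.9 and chromosome 5 with 34.6% ± 11.1. Chromosome 4 and X exceeded the other bins by 16.3 and 11.4 percentage points, in 32 of 32 cells each, and chromosome 5 exceeded them by 8.83 points in 30. The lowest shares were those of the chromosome given as 22:9 (0.401% ± 0.539), chromosome 19 (2.28% ± 1.97) and chromosome 17 (6.21% ± 3.20), all below the other bins in 32 of 32 cells. Chromosome 15, measured without its part at 61000001 to 89900000, had a share of 19.2% ± 9.68. Sign-flip permutation tests placed 9 of the 22 chromosomes above and 12 below the other bins, with a smallest adjusted p of 1.57e-05. Chromosome 14 was not separated from them (24.2% against 26.4%, adjusted p = 0.124). Chromosome 11 passed by 3.02 points (adjusted p = 0.0143, higher in 21 of 32 cells), but not without the 8 sparsest cells (2.65 points, adjusted p = 0.0874) or without bins of low expected reads (2.32 points, adjusted p = 0.0504), within a range of adjusted p from 0.00104 to 0.0874 over 8 alternatives.

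The chromosomes were made up of the contact classes in different proportions. On chromosome 4, 20.3% of the bins were in contact in at least 80% of the cells and 22.1% in none, and on X the proportions were 15.9% and 24.7%. On chromosome 17, 79.2% of the bins were in contact in no cell and 1 bin reached 80%. On 22:9, 92.6% of the bins were never in contact and the highest contact frequency of any bin was 15.6%.

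**Figure D3:**
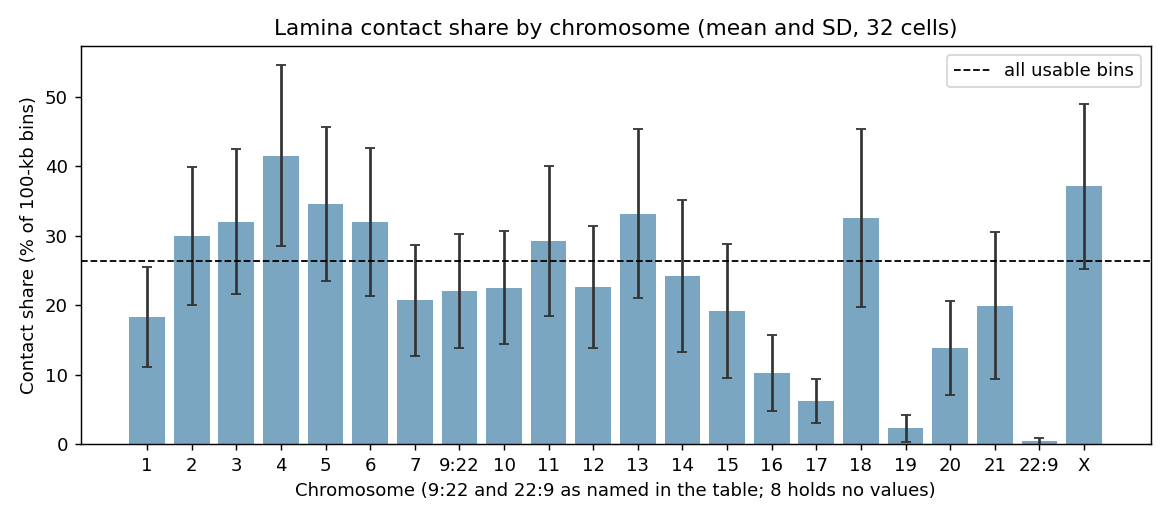
Contact share (% of 100-kb bins, vertical axis) of each chromosome with values (horizontal axis), as the mean (bar) and SD (error bar) over 32 cells, with the dashed line at the mean over all used bins (26.3%). Chromosome 4 is highest at 41.5% and 22:9 lowest at 0.401%.

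Chromosomes 18 and 19 are of similar size, and chromosome 18 is poor and chromosome 19 rich in genes. Gene density was not analysed, and this pair alone does not show a relation to it. Chromosome 18 had 32.5% ± 12.8 of its bins in contact and chromosome 19 had 2.28% ± 1.97 (SD, n = 32). The difference within a cell was 30.2 percentage points ± 12.3 (SD), with chromosome 18 higher in 32 of 32 cells (sign-flip permutation test, p = 1e-05, the smallest the resamples can give). On chromosome 18, 288 of 751 bins were called in contact more often than expected, and on chromosome 19 it was 5 of 560. No bin of chromosome 19 was in contact in more than 53.1% of the cells, and 85.9% of its bins were in contact in none.

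**Figure D4:**
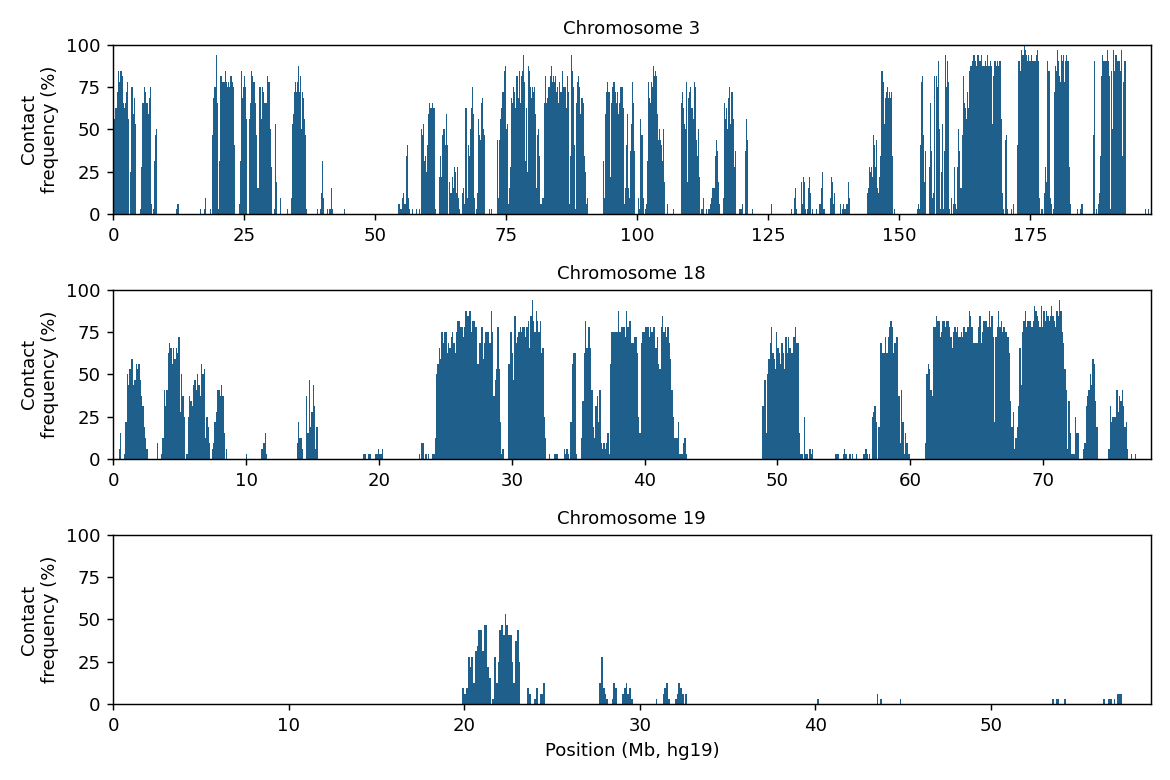
Contact frequency (% of 32 cells, vertical axis) of each 100-kb bin along chromosomes 3, 18 and 19 (horizontal axis, position in Mb, hg19). Chromosome 3 reaches 100% in its long arm, chromosome 18 reaches 93.8%, and chromosome 19 reaches 53.1%.

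The longest stretches with an OE of at least 1 in nearly every cell lay on chromosome 3. A stretch of 4.5 Mb (163200001 to 167700000) had a mean contact frequency of 89.0% and a mean OE of 5.22 ± 2.11 (SD, n = 32). A second, of 4 Mb (172600001 to 176600000), had a contact frequency of 91.3% and an OE of 5.89 ± 1.93. Its flanks, the bins within 1 Mb, had a contact frequency of 7.19%, whereas the flanks of the other 7 named stretches had 37.7 to 76.4%, with 71.1% beside the longest. Chromosome 3 held 2 more of the 8 longest stretches, at 190800001 to 192500000 (1.7 Mb, 92.8%) and 167900001 to 169300000 (1.4 Mb, 89.5%). The others lay on X (32100001 to 34100000, 2 Mb, 85.9%), on chromosome 4 (126400001 to 128100000, 1.7 Mb, 87.7%, and 136000001 to 137600000, 1.6 Mb, 86.3%) and on chromosome 1 (215900001 to 217200000, 1.3 Mb, 86.5%). The mean OE of the named stretches outside chromosome 3 was 3.31 to 3.81. On the distal long arm of chromosome 3 the bins that were never in contact also had higher values, 2.01 times the mean OE of such bins elsewhere (95% bootstrap interval over 29 cells 1.78 to 2.24), and 1.64 times (1.45 to 1.87) with bins matched on distance to contacted bins. The ranking of stretches was not corrected for this, and 4 of the 8 lie there. In all, the bins at 80% or more formed 1014 stretches with a median length of 0.1 Mb, of which 17 reached 1 Mb. Without the 3 shallow cells there were 1054 with a median of 0.2 Mb, and 77 reached 1 Mb. The longest 2 were then the same stretches of chromosome 3, but only 4 of the longest 8 overlapped a named stretch, and stretches of 3.1 Mb on chromosomes 4 (27500001 to 30600000), 5 (25800001 to 28900000), 11 (39400001 to 42500000) and 18 (68400001 to 71500000) took the other places.

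At the OE limit of 1, stretches in contact in no cell were longer, and stretch lengths were not computed under other limits. The longest was 19.7 Mb on the short arm of chromosome 19 (200001 to 19900000), where 551 reads were recovered over all cells and the mean OE was 0.0153 ± 0.0122 (SD, n = 32). Chromosome 19 also held a stretch of 8.6 Mb (44900001 to 53500000). Chromosome 1 held stretches of 13.5 Mb (17200001 to 30700000) and 8.8 Mb (35900001 to 44700000), and chromosome 3 one of 10.2 Mb (44200001 to 54400000). The first 9 Mb of chromosome 4 (1 to 9000000) were also never in contact, on the chromosome with the highest share. The remaining named stretches were 8.8 Mb on chromosome 6 (29500001 to 38300000), which spans the classical major histocompatibility complex, and 8.5 Mb at the end of chromosome 17 (72700001 to 81195210). In all, 1596 stretches of never-contacted bins had a median length of 0.25 Mb, and 294 reached 1 Mb. Without the 3 shallow cells, all of the longest 8 overlapped a named stretch.

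Both the centromere regions and the chromosome ends, pooled over chromosomes, were in contact less often than the remaining bins. They were not compared within each chromosome. Such regions take up more of a short chromosome, and several short chromosomes had low shares, so part of the differences may come from the chromosomes. Within 5 Mb of a chromosome end, 7.65% ± 2.76 of 1918 bins were in contact (SD, n = 32), and within 5 Mb of a centromere 18.5% ± 6.34 of 1713 bins. The remaining 22953 bins had a share of 28.5% ± 8.72. The differences from the rest were -20.8 and -9.97 percentage points, in the same direction in 32 of 32 cells (sign-flip permutation tests, adjusted p = 1e-05 for both, the smallest the resamples can give). Bins within 2 Mb of an end had a share of 5.24% and bins within 10 Mb 14.4%, and near the centromere these shares were 19.3% and 18.1%.

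Contacts in a single cell ran over long uninterrupted stretches of bins. The values do not separate the 2 copies of a chromosome or different times, so a run need not be 1 contact of 1 copy. The mean run of contacted bins was 471 kb ± 156 (SD, n = 32), against 316 kb (315 to 317) in randomised tables that kept each bin's contact frequency and each cell's contacts per chromosome. A cell had 201 ± 82.1 runs of at least 1 Mb, against 147, and its longest run was 6.44 Mb ± 2.54, against 4.47 Mb. Each difference was larger than in any randomisation (p = 0.0099, the smallest that 100 randomisations can give). The excess in mean run length, 155 kb, was 91.5 kb with any read counted, and in the 29 deeper cells it was 168 kb with all reads and 84.7 kb after thinning. That in the longest run, 1.96 Mb, was 0.630 Mb with runs joined across 1 bin and 3.06 Mb with any read counted (p = 0.0099 for each). The excess of runs of at least 1 Mb, 54.6 per cell, was 28.1 with an OE limit of 0.5 (p = 0.0099) and was not kept when runs were joined across 1 bin (-7.49 per cell, p = 0.0099) or when any read counted as contact (-2.18 per cell, p = 0.129), with p from 0.0099 to 0.129 over 10 alternatives.

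Bins of intermediate contact frequency had an OE of at least 1 in the same cells more often when they lay on the same chromosome, and more so the closer they were. Reads in never-contacted bins of a chromosome also moved with its contact share over cells (slope of 0.692 on the log2 scale, 95% bootstrap interval 0.546 to 0.860), and the correlations were not corrected for this. Among the 8468 bins of 20 to 80% contact frequency, the mean correlation of contacts over cells was 0.444 for bins up to 1 Mb apart, against 0.162 in randomised tables. It was 0.302 against 0.158 at 1 to 5 Mb, 0.232 against 0.155 at 5 to 20 Mb, 0.197 against 0.152 at 20 to 50 Mb and 0.177 against 0.154 beyond 50 Mb (adjusted p = 0.0119 for each of the 5 distances). Observed and randomised levels were both lower without the 3 shallow cells. They were then 0.389 against 0.0469 up to 1 Mb, 0.0685 against 0.0459 beyond 50 Mb and 0.0418 against 0.0461 on different chromosomes. With any read counted, the excess up to 1 Mb was 0.154 in place of 0.283, that at 1 to 5 Mb 0.0803 in place of 0.144, that at 5 to 20 Mb 0.0436 in place of 0.0766 and that at 20 to 50 Mb 0.0282 in place of 0.0450. For bins on different chromosomes it was 0.151 against 0.152, a difference of -0.00102 that did not pass (adjusted p = 0.0891). That small difference was sensitive to the processing, at -0.00433 (p = 0.0099) without the 3 shallow cells and 0.00275 (p = 0.0099) with an OE limit of 2, within a range of p from 0.0099 to 0.109 over 10 alternatives. The randomised tables keep the total contacts of each cell, so an excess on the same chromosome by itself tends to lower the value between chromosomes. That value therefore does not test whether contacts of different chromosomes are coordinated.

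**Figure D5:**
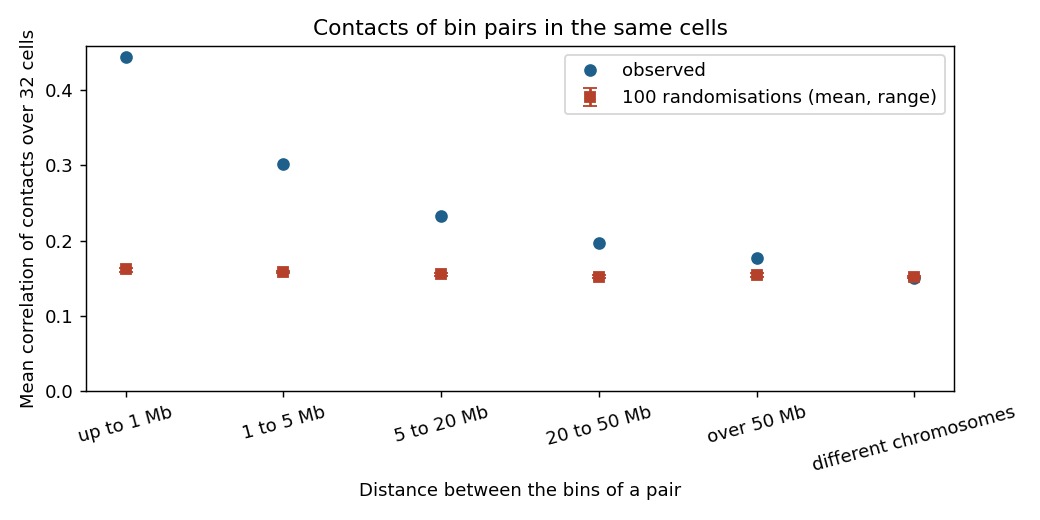
Mean correlation over 32 cells of the contacts of pairs of bins (vertical axis) by the distance between the bins (horizontal axis), for the 8468 bins of 20 to 80% contact frequency. Circles are the observed means, from 0.444 up to 1 Mb to 0.151 on different chromosomes, and squares with bars are the mean and range of 100 randomised tables, where the means lie between 0.152 and 0.162.

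At the OE limit of 1, pairs of cells shared about as many contacted bins as they differed in. The median Jaccard overlap, the shared contacts over all contacts of a pair of cells, was 0.514 over 496 pairs (0.0564 to 0.683), and 0.529 over the 406 pairs of the 29 deeper cells (0.352 to 0.683). Over all cells the median was 0.368 with an OE limit of 2, 0.582 with a limit of 0.5 and 0.587 with any read counted. Overlaps varied between pairs more than in the randomised tables, with an SD of 0.174 against 0.162 in all cells and 0.0690 against 0.0413 in the 29 deeper cells (p = 0.0099 for both, the smallest the randomisations can give). The randomised tables do not keep the correlation of neighbouring bins, which by itself raises this SD, so groups of more similar cells are not shown. The excess of the SD, 0.0126 in all cells, was 0.00260 with any read counted and 0.0345 without the 8 sparsest cells.

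Contact frequency and the OE of the contacting cells come from the same values with a limit at 1, so a relation between them arises in part by construction, and it is given as a description. Across 12774 bins in contact in at least 3 cells, which are not independent replicates, Spearman's rho between them was 0.741, and it was 0.901 with any read counted and 0.502 with an OE limit of 2. The median of the mean OE in contacting cells was 1.68 in bins under 20% contact frequency, 2.79 at 20 to 80% and 3.85 at 80% or more.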

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

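Leaving out the 3 shallow cells, thinning and leaving out bins of low expected reads were alternatives chosen after the data were seen. Of the values recomputed, 15 could not change, since bins at 0 in every cell hold no contact and chromosomes 18 and 19 are autosomes, and 1 was of another measure (Pearson's r of 0.678 beside a Jaccard overlap of 0.514). Of the rest, 360 kept their direction and their side of the threshold or, without a test, stayed within 1.5 times for counts and 1 SD for the contact share and the median overlap of cells, 8 moved further, 5 newly passed, 2 no longer passed and 4 reversed. The SDs used, 8.08 for the share and 0.174 for the overlap, include the shallow cells and were 3.99 and 0.0690 in the 29 deeper cells. By the smaller SDs, values counted among the 360 would have moved. These are the share of 33.1% with an OE limit of 0.5, and the overlaps of 0.368 with a limit of 2 and 0.587 with any read counted. The 360 included chromosome 18 against 19 (21.2 to 41.3 points), the centromere (-14.0 to -7.30 points), the chromosome ends (-25.8 to -14.6 points), the mean run excess (84.7 to 173 kb) and the excess correlation up to 1 Mb (0.154 to 0.349), under every alternative that could change them. With any read counted, the contact share was 44.6%, 7099 bins reached 80%, 1204 bins were never in contact, the excess of runs of at least 1 Mb turned to -2.18 (p = 0.129, from 54.6), and the excess correlation between chromosomes turned from -0.00102 to 0.00175. With an OE limit of 2 these were 17.2% for the share, 261 bins and 0.00275, and with 0.5 they were 4758 bins and -0.00334. Without the 3 shallow cells 3774 bins reached 80% and the excess between chromosomes was -0.00433, and without the 8 sparsest cells these were 4018 bins and -0.00679. The excess between chromosomes was -0.0035 with thinned reads and -0.00883 for bins of 30 to 70% contact frequency, and under all 7 of these alternatives it passed its test (p = 0.0099 to 0.0198). Because the randomised tables keep the total contacts of each cell, passing does not show coordination between chromosomes or its absence. Joining runs across 1 bin turned the excess of runs of at least 1 Mb to -7.49. Chromosome 11 no longer passed without bins of low expected reads (2.32 points) or without the 8 sparsest cells (2.65 points). A higher limit or a shallow cell leaves fewer cells in contact by construction, and for the other changes the cause was not tested. The gene density and gene list analyses with their alternatives, and chromosome 8 with part of chromosome 15, were not run, and restriction to autosomes was not applied to the comparison of chromosomes. No paired analysis was possible because the cells form 1 group with no other to pair them with, and the pairing in the tests is of regions within each cell. Depth limits the 3 shallow cells most, since 1 read in a bin is a contact there.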

Other observations

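Single cells differed in the share of a given chromosome with an OE of at least 1, which differences in copy number would also change. Among the 29 deeper cells, the share of chromosome 18 in contact ranged from 9.19 to 47.0%, that of chromosome 21 from 5.06 to 38.8%, that of chromosome 13 from 15.4 to 52.4% and that of chromosome 4 from 31.0 to 57.1%. On 21 of 22 chromosomes, the deviation of cells from the share given by their total contacts was larger than in all 100 randomised tables, by a median factor of 6.53 over the 22 chromosomes (1.20 to 8.14). The randomised tables do not keep the correlation of neighbouring bins, which by itself widens this spread. The factor therefore does not show that whole chromosomes vary between cells. The exception was 22:9, where shares were 0 to 2.03% and 5 of the 100 randomised tables gave a spread as large. The short and long arms of a chromosome deviated together, with a median correlation over cells of 0.243 on 17 chromosomes, above 0 on 16 of them, against a highest value of 0.140 in randomised tables (p = 0.0099, the smallest they can give), and chromosome 11 had the highest correlation (0.663). Reads in never-contacted bins of the 2 arms also correlated, with a median of 0.288, so these values do not separate lamina contact from the number of chromosome copies.

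Bins in contact in at least 20% of the cells formed 1015 stretches with a median length of 0.5 Mb, and the longest was 10.3 Mb.

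In the paragraphs that follow, the outcome that would decide each test was written before it was run, but the patterns had been seen in the same data, and the tests of the 29 deeper cells and of thinned reads were chosen after the data were seen. The design has 1 group, so no biological explanation was tested.

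Cells with more reads had a larger contact share. Depth itself was argued against as the cause, since r was 0.838 after every cell was thinned to 40279 reads (permutation p = 1e-05, the smallest the resamples can give). The relation of mean run length to reads, r = 0.841 with all reads, was 0.253 after thinning (p = 0.187), so for run length an effect of depth remains open. Cells with more contacts may yield more amplified fragments and so more reads, or fragments lost in a cell before amplification may lower both, and neither was tested.

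Contacts on the same chromosome tended to occur in the same cells. Fragments shared across a bin border were argued against, since bins 3 positions apart kept 0.834 of the excess correlation of adjacent bins, and so was depth as the whole cause, since the excess up to 1 Mb was 0.248 with the 29 deeper cells thinned to one depth, against 0.342 with all their reads. Differences between cells in the copy number of whole chromosomes may contribute over long distances, because log2 reads in never-contacted bins of a chromosome moved by 0.692 (95% bootstrap interval 0.546 to 0.860) per log2 unit of its contact share. Whether weak contacts that reach the never-contacted bins give that slope cannot be told apart from copy number, as the slope was 0.502 (0.299 to 0.733) in bins over 2 Mb from contacted regions, on few reads. The reads of both arms in never-contacted bins correlated with a median r of 0.288 over 17 chromosomes, above the highest of 1000 permutations (0.172) but short of the value set for copy number.

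The distal long arm of chromosome 3, from shortly before the first named stretch there to the chromosome end, had higher values than contacted regions elsewhere. It was picked for them, so no test of the difference itself is reported. In the 29 deeper cells its bins at 80% or more had a mean OE of 5.39 ± 1.53 (SD), against 3.19 ± 0.378 in such bins elsewhere, higher in 28 of 29 cells. Low expected reads were argued against, with a ratio of 0.994 to contacted bins elsewhere. Never-contacted bins matched on distance to contacted bins, in coarse classes, kept a ratio of 1.64 (1.45 to 1.87). On the rest of chromosome 3 it was 1.08 (0.950 to 1.22), so a difference in distance alone was argued against. The matching left out how high the OE of the nearby contacted bins was. It therefore cannot tell extra copies of that segment, a candidate explanation, apart from weak contacts that reach the never-contacted bins. The ratio of 2.01 (1.78 to 2.24) over all never-contacted bins was higher and was not matched on distance, and the number of copies was not determined. On that hypothesis, the contact frequencies of the chromosome 3 stretches named above would be raised by copy number.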
